A study of Homo sapiens with 6 samples.

How the data were processed

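Total RNA from MCF-7 cells transfected with a control siRNA (siNC) or siRNA against TRIM8 (siTRIM8) was sequenced, with 3 libraries per group. Groups and replicate numbers were taken from the sample titles, and the design text of the series calls the replicates biological. The deposited table holds 1 column per library and 60623 gene identifiers. Its header names no unit. The deposited values were read as TPM because every column summed to nearly the same total, between 987966 and 990811, and they are rounded to 2 decimals. A near-constant total does not by itself show a correction for length. HISAT2 2.1.0, RSEM 1.3.1, DESeq2 1.24.0 and the build GRCh38.p13 are named, without roles, per the submitters' processing notes. Which step made the TPM values, the annotation and the strand setting are not given in the sources used here. TPM divides by transcript length and by the library's total, so a rise of abundant transcripts lowers the rest, and it keeps no read depth.

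Gene symbols were matched by identifier for 60295 of the 60623 entries. Coordinates and gene types come from GENCODE release 29 on GRCh38, whose chromosome coordinates patch releases leave as they are.

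Genes with a mean of at least 1 TPM over the 6 libraries (14262) were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend on mean expression), two-sided, with Benjamini-Hochberg adjustment over the genes tested and no block. A gene was called at an adjusted p under 0.05. The model has 4 residual degrees of freedom. A count-based test was not used, since TPM values are not read counts. TRIM8 was also tested with an exact permutation test.

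Gene lists were tested with camera (preset correlation 0.01) where at least 5 members were tested, which was so for 24 of 25 lists, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For each list, genes were also adjusted over the list alone. The lists, the tests, the rule for naming genes and the alternatives other than those named below as later were fixed before the data were examined.

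The genes named are TRIM8, the 10 genes with the largest and the 10 with the most negative log2 fold change among called genes whose groups do not overlap (leaving out names that are clone or locus identifiers), and from each list up to 4 members with the smallest p-values. Others are said to have been named after their values were seen.

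On simulated data for the 14262 genes of this comparison, with 200 changed, the same steps called 32% of genes changed by a log2 fold of 0.5, 74% at 1, 84% at 1.5 and 98% at 2, and 3 of 147 calls were false. The simulation drew genes independently and gave both groups the same spread. It also changed far fewer genes than were called in the data, so these shares need not hold for the real comparison. The alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean of 10 TPM, median-of-ratios scaling, quantile normalization, a replicate block, eBayes without a trend and with robust estimation, an estimated correlation for the lists, and each library left out in turn. Chosen after the data were seen were siTRIM8 replicates 2 and 3 left out together, and a spline trend (4 degrees of freedom) on GC content and length removed from each library, for which 99.2% of the tested genes had values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.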

Results

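RNA sequencing was performed on MCF-7 cells, an established human breast cancer line of luminal type that carries the estrogen receptor. The cells were transfected either with a control siRNA (siNC, 3 libraries) or with siRNA against TRIM8 (siTRIM8, 3 libraries), and the design text of the series calls the replicates biological. TRIM8 is a ubiquitin ligase of the tripartite motif family. The deposited values, given without a unit, were read as TPM, transcript abundances corrected for length and scaled to a fixed total. They covered 60623 genes, of which 28698 were above 0 in at least 1 library and 14262 had a mean of at least 1 TPM and were tested. The TPM summed to between 987966 and 990811 per library and between 13868 and 14420 genes reached 1 TPM. Read depth is unknown, since TPM keeps no depth, and no counting interval is given for that reason. All fold changes are siTRIM8 minus siNC on the log2(TPM + 1) scale, which understates the change of genes at low levels.

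The comparison of siTRIM8 with siNC asked which transcripts differ when TRIM8 is depleted. The target itself fell to 8.58% of its control level. Many estrogen-induced genes were higher in all 3 siTRIM8 libraries, among them GREB1 and AREG, while GATA3, FOXA1 and ERBB2, of the luminal identity genes, were lower and ESR1 was higher. Of the tested genes of hypoxia and glycolysis 20 of 22 were higher, of the targets of the stress factor ATF4 13 of 20, and of the endoplasmic reticulum chaperone genes 12 of 16. Interferon-stimulated genes were far higher in siTRIM8 replicates 2 and 3 and less shifted in siTRIM8 replicate 1. No list kept its call when the correlation between genes was estimated.

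TRIM8 (ENSG00000171206) lies on chromosome 10 from 102642310 to 102660680 on the plus strand of GRCh38 and is annotated as protein coding. Its level was 37.84, 37.58 and 40.74 TPM in the siNC libraries and 3.2, 2.88 and 3.89 TPM in the siTRIM8 libraries. The means were 38.7 ± 1.75 and 3.32 ± 0.516 TPM (SD, n = 3 each), an 11.7-fold lower level. The log2 fold change was −3.21 (SE 0.10, limma adjusted p = 4.69e-05). A two-sided exact permutation test on the same 6 values gave p = 0.1, the smallest p that 3 against 3 libraries allow.

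**Figure D1:**
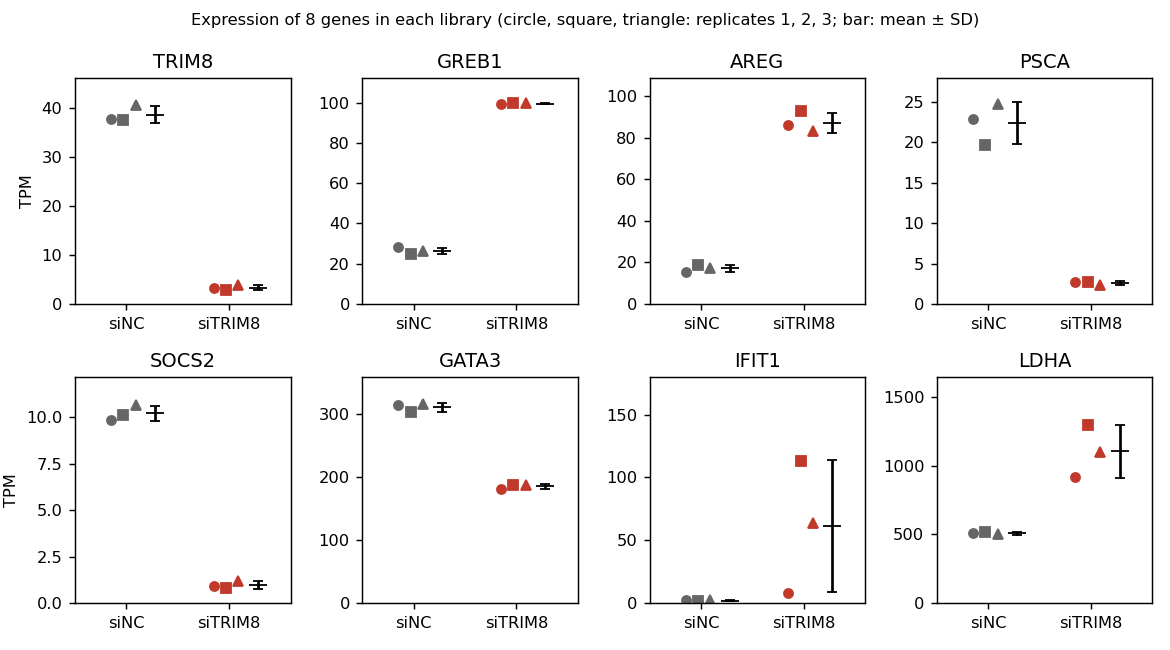
Expression in TPM (vertical axis, starting at 0, with its own scale in each panel) of 8 genes in the 3 siNC libraries (grey) and the 3 siTRIM8 libraries (red). Circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean ± SD. TRIM8 fell from 38.7 to 3.32 TPM, GREB1 rose from 26.3 to 99.6 TPM, and IFIT1 ranged from 7.68 to 113 TPM among the siTRIM8 libraries.

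At a limma adjusted p under 0.05 (Benjamini-Hochberg over 14262 genes), 4776 genes differed, 1769 of them higher and 3007 lower in siTRIM8. At least 2-fold changes were found for 354 of them, 130 higher and 224 lower. These were 161 and 180 under median-of-ratios scaling, 171 and 169 under quantile normalization, and 202 and 227 without siTRIM8 replicate 1. They were 185 and 459 (644 in all) with a pseudocount of 0.1, 51 and 53 (104) with a pseudocount of 5, and 68 and 80 (148) with a minimum mean of 10 TPM. The number of called genes was 3083 without siNC replicate 2 and 3176 without siTRIM8 replicate 3. With siTRIM8 replicate 1 as the single siTRIM8 library, an alternative chosen after the data were seen, it was 2592 (999 higher and 1593 lower). In that fit, here and below, the siNC libraries alone give the spread and the lone siTRIM8 library is assumed to vary like them, so its calls are not replicated in siTRIM8. The balance of directions depended on scaling and, for 2-fold changes, on the pseudocount and the filter. Median-of-ratios scaling called 2590 genes higher and 2136 lower, and quantile normalization 2177 higher and 2400 lower. Removing a trend on GC content and transcript length, an alternative chosen after the data were seen, called 2415 higher and 2134 lower. The median log2 fold change of all tested genes was −0.07 as deposited. Counts of list members given below are to be read against the 1769 higher and 3007 lower among all 14262 tested genes. Values of the groups did not overlap for 49.4% of the tested genes, against 10% by chance. The first principal component held 47.8% of the variance and separated the groups, and the second, with 16.7%, set siTRIM8 replicate 1 (−32.1) apart from siTRIM8 replicates 2 (15.8) and 3 (14.0).

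Of 42 tested estrogen-induced genes, 31 rose, 1 fell and 10 did not pass the test. The counts adjusted over the list alone were also 31 and 1. GREB1, a growth-promoting cofactor of the estrogen receptor, rose from 26.3 ± 1.70 to 99.6 ± 0.278 TPM (log2 fold change 1.88, SE 0.06, adjusted p = 4.69e-05). AREG, a ligand of the EGF receptor, rose by 2.29 and PKIB, an inhibitor of protein kinase A, by 1.26 on the log2 scale. The ubiquitin ligase gene SIAH2 had a 2.49-fold higher mean TPM. The gene that fell was OLFM1 (−0.44, adjusted p = 0.00266), named after its values were seen. The median log2 fold change of the list was 0.53 and camera, with its preset correlation, gave adjusted p = 1.59e-15. The call was lost with an estimated correlation (adjusted p = 0.141 with an estimated correlation). Per library, the median over the siNC mean was 0.45, 0.60 and 0.50 in siTRIM8 replicates 1, 2 and 3. With siTRIM8 replicate 1 as the single siTRIM8 library, and the spread from siNC alone, 20 members rose and 1 fell.

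Among 21 tested luminal identity genes, 13 fell, 1 rose and 7 did not pass. Adjusted over the list alone, 15 fell and 1 rose. GATA3, a transcription factor of the luminal lineage, went from 311 ± 7.18 to 185 ± 4.08 TPM (log2 fold change −0.74, adjusted p = 0.000116). The receptor tyrosine kinase gene ERBB2 fell by 1.08, the pioneer factor gene FOXA1 by 0.68 and the ETS factor gene SPDEF by 0.75 on the log2 scale. ESR1, which encodes the estrogen receptor and was named after its values were seen, was the member that rose, from 43.9 ± 2.90 to 65.4 ± 10.7 TPM (0.55, adjusted p = 0.0127). That call was lost with siTRIM8 replicate 1 as the single siTRIM8 library, where the spread comes from siNC alone and 0 members rose and 14 fell. The list's median was −0.31, with camera adjusted p = 9.94e-05 and adjusted p = 0.350 with an estimated correlation. Under median-of-ratios scaling 9 members were lower and 1 higher.

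**Figure D2:**
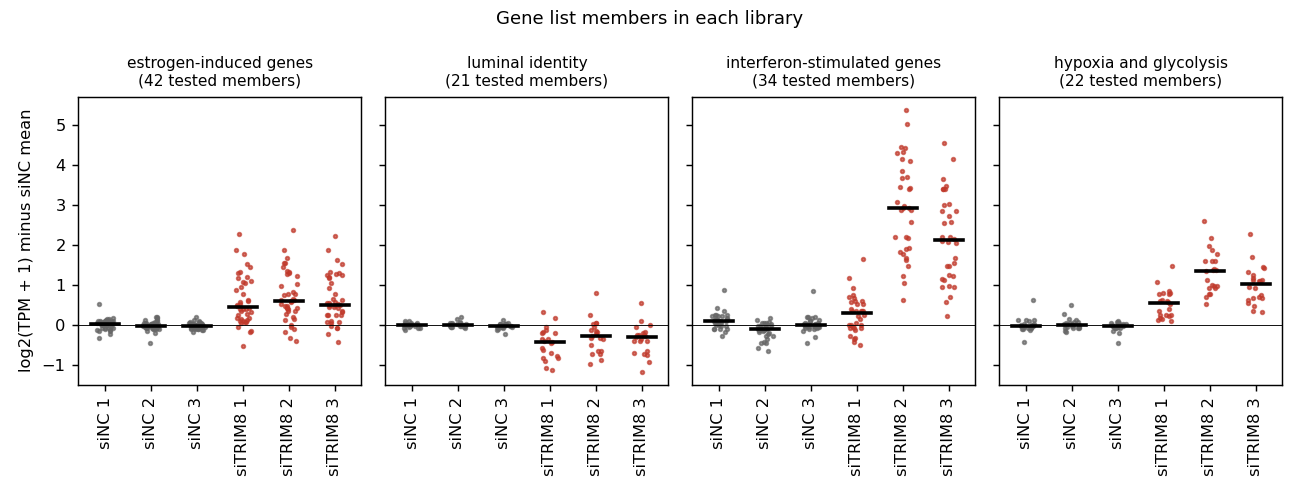
Members of 4 gene lists in each library, as log2(TPM + 1) minus the siNC mean of the same gene (vertical axis); each point is a gene, black bars are medians, siNC is grey and siTRIM8 red. The medians of the interferon-stimulated genes were 0.31, 2.92 and 2.13 in siTRIM8 replicates 1, 2 and 3, while those of the estrogen-induced genes were 0.45, 0.60 and 0.50.

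Besides TRIM8, the genes with the most negative changes included PSCA, a surface antigen anchored in the membrane, on chromosome 8, which fell from 22.4 ± 2.58 to 2.58 ± 0.246 TPM (log2 fold change −2.70, adjusted p = 6.81e-05). SOCS2, a feedback inhibitor of cytokine receptors, fell from 10.2 ± 0.404 to 0.967 ± 0.214 TPM (−2.52, adjusted p = 9.34e-05). ABCA4, a retinoid transporter, fell by 2.19, the lectin gene CLEC3A by 2.08, GNG12, a G protein gamma subunit, by 2.01 and SERHL2 by 1.99 on the log2 scale. The pseudogene EFCAB3P1 fell by 2.32 on that scale. RNU1-1 and RNU1-4, copies of the U1 small nuclear RNA gene, were listed with identical values in every library and a log2 fold change of −2.89 each. They can share reads, were listed at 0 in 2 siTRIM8 libraries, and are uncertain. The call of RNU1-1 was lost without any 1 of the siNC libraries (adjusted p = 0.0542, 0.0602 and 0.0516), without siTRIM8 replicate 3 (adjusted p = 0.0587) and without the filter on low values (adjusted p = 0.0522). The higher genes by size were 8 interferon-stimulated genes, the pseudogene FAUP4 and LOX. LOX, the enzyme that crosslinks collagen, rose from 2.03 ± 0.655 to 14.6 ± 5.73 TPM (2.32, adjusted p = 0.00181). FAUP4 had a log2 fold change of 2.33 (adjusted p = 0.0106) and is uncertain, since its reads can be shared with the parent gene. Its call was lost with siTRIM8 replicate 1 as the single siTRIM8 library (adjusted p = 0.0764).

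Of 34 tested interferon-stimulated genes, 12 rose, 0 fell and 22 did not pass. Adjusted over the list alone, 19 rose and 0 fell. IFIT1, an antiviral protein that binds foreign RNA, stood at 7.68, 113 and 63.4 TPM in siTRIM8 replicates 1, 2 and 3, against 1.78 ± 0.560 TPM in siNC (log2 fold change 3.87, SE 0.87, adjusted p = 0.0157). The ubiquitin-like modifier gene ISG15 stood at 69.4, 923 and 485 TPM, against 45.9 ± 11.1 TPM in siNC (2.78, adjusted p = 0.0464). IFIT3 rose by 3.45, OAS1 by 3.01, IFI6 by 2.82, IFIT2 by 2.75, OASL by 2.46, IFI44L by 2.35, HERC6 by 1.91 and ISG20 by 0.84 on the log2 scale. The list's median was 1.83, with camera adjusted p = 9.36e-09 and adjusted p = 0.420 with an estimated correlation. Fry did not call the list (fry adjusted p = 0.121). The spread came from siTRIM8 replicate 1. Without it, 33 members rose and 0 fell (median 2.52), and with it as the single siTRIM8 library, an alternative chosen after the data were seen, 3 rose and 0 fell (median 0.31). Camera called the list there (adjusted p = 0.00843), but with the spread from siNC alone this is no replicated evidence of a shift in that library. Leaving out siNC replicate 1, siNC replicate 2 or siTRIM8 replicate 3 left 0 members called, leaving out siNC replicate 3 left 1, and leaving out siTRIM8 replicate 2 left 2. The number that rose was 1 without the filter on low values, 4 in the fit without a trend, 5 in the robust fit, 6 with a pseudocount of 5 and 9 with the replicate block, and 16 with a pseudocount of 0.1. OAS1, IFI6, ISG15, IFIT2, OASL and IFI44L lost their calls without the filter, without a trend and in the robust fit. The number of members above all 3 siNC libraries was 18, 34 and 34 in siTRIM8 replicates 1, 2 and 3. Each of the 8 interferon-stimulated genes among the largest increases lost its call without siNC replicate 1, without siNC replicate 2 and without siTRIM8 replicate 3 (IFIT1 at adjusted p = 0.0519, 0.0572 and 0.0599), and so did ISG20 and HERC6.

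Of 22 tested genes of hypoxia and glycolysis, 20 rose, 0 fell and 2 did not pass, with 21 and 0 adjusted over the list alone. LDHA, which makes lactate from pyruvate, rose from 509 ± 10.7 to 1104 ± 191 TPM (log2 fold change 1.10, adjusted p = 0.00108). ADM, a vasodilator peptide gene, rose by 2.12, the mitophagy receptor gene BNIP3 by 1.10 and the oxygen sensor gene EGLN1 by 0.70 on the log2 scale. The list's median was 0.94, with camera adjusted p = 7.12e-11 and adjusted p = 0.350 with an estimated correlation. Like the interferon-stimulated genes, the list was least shifted in siTRIM8 replicate 1 (0.55, against 1.36 and 1.03 in replicates 2 and 3). With that replicate as the single siTRIM8 library, and the spread from siNC alone, 12 members rose and 0 fell, and 12, 13 and 12 rose without siNC replicate 1, siNC replicate 3 and siTRIM8 replicate 3. Without the filter on low values 12 rose.

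Targets of ATF4, the transcription factor of the integrated stress response, rose in 13 of 20 cases, 1 fell and 6 did not pass (14 and 1 adjusted over the list alone). MTHFD2, a mitochondrial folate enzyme, rose from 117 ± 5.04 to 204 ± 7.13 TPM (log2 fold change 0.80, adjusted p = 0.00024). The amino acid transporter subunit SLC7A5 rose by 1.22 and the serine synthesis enzyme PSAT1 by 0.86 on the log2 scale, and SLC3A2, the partner of SLC7A5, had a 2.01-fold higher mean TPM. ATF5, named after its values were seen, was the member that fell (−0.90). The median was 0.69, with camera adjusted p = 1.77e-07 and adjusted p = 0.350 with an estimated correlation. The list was also least shifted in siTRIM8 replicate 1 (0.38, against 0.85 and 0.74 in replicates 2 and 3), and with it as the single siTRIM8 library, and the spread from siNC alone, 8 members rose and 1 fell. Of 16 endoplasmic reticulum chaperone and unfolded protein response genes, 12 rose, 0 fell and 4 did not pass (12 higher and 1 lower adjusted over the list alone). HSPA5, the main chaperone of that compartment, rose from 135 ± 6.78 to 281 ± 18.3 TPM (1.05, adjusted p = 0.00021), and SDF2L1, HSP90B1 and PDIA6 rose by 0.60, 0.46 and 0.37 on the log2 scale. The median was 0.38, with camera adjusted p = 5.91e-08 and adjusted p = 0.292 with an estimated correlation.

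Of 32 genes of the G1/S transition and DNA replication, 15 rose, 1 fell and 16 did not pass (17 and 1 adjusted over the list alone). The replication factor genes CDC45 and ORC1 rose by 0.48 and 0.52, the ribonucleotide reductase subunit RRM2 by 0.40 and the transcription factor gene E2F1 by 0.39 on the log2 scale, while CCNE1, which encodes cyclin E1 and was named after its values were seen, fell by 0.33 on that scale. The CCNE1 call was lost under median-of-ratios scaling and quantile normalization, with the GC and length trend removed, without the filter, without a trend, with the replicate block and with siTRIM8 replicate 1 as the single siTRIM8 library. It was also lost without any 1 of the siNC libraries and without siTRIM8 replicate 2 or 3, where 0 members fell. Without siNC replicate 2, siNC replicate 3 or siTRIM8 replicate 3 the number that rose was 9, 9 and 8. The list's median was 0.22, with camera adjusted p = 1.77e-07 and adjusted p = 0.350 with an estimated correlation. Of 37 genes of G2/M and mitosis, 17 rose, 0 fell and 20 did not pass (20 and 0 adjusted over the list alone). The mitotic kinases AURKB, AURKA and CDK1 rose by 0.37, 0.46 and 0.40, and the cyclin gene CCNA2 by 0.41 on the log2 scale. The median was 0.20, with camera adjusted p = 7.68e-09 and adjusted p = 0.350 with an estimated correlation.

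**Figure D3:**
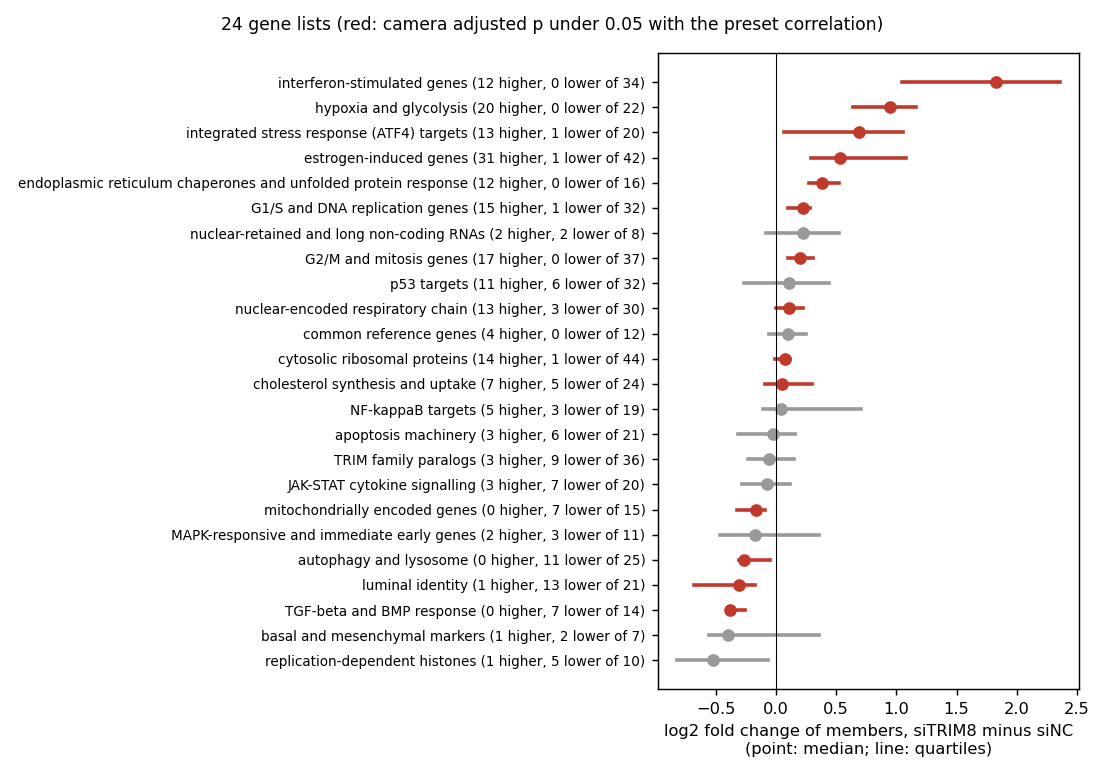
Median (point) and quartiles (line) of the log2 fold changes of the tested members of 24 gene lists (horizontal axis, siTRIM8 minus siNC), with counts of members higher and lower at a limma adjusted p under 0.05. Red marks the 14 lists with a camera adjusted p under 0.05 at the preset correlation, and 0 lists kept the call with an estimated correlation.

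Nuclear-encoded respiratory chain genes were higher in 13 of 30 cases, lower in 3 and did not pass in 14 (15 and 3 adjusted over the list alone). The complex III subunits UQCRC2 and CYC1 rose by 0.39 and 0.34, COX6C by 0.43 and the complex II subunit SDHB by 0.36 on the log2 scale. Without siNC replicate 1 the number that rose was 8. The median was 0.11, with camera adjusted p = 7.13e-05 and adjusted p = 0.145 with an estimated correlation. Of 15 mitochondrially encoded genes, 7 fell, 0 rose and 8 did not pass (7 lower and 1 higher adjusted over the list alone). The ribosomal RNA MT-RNR2 fell by 0.55, MT-CO1 by 0.34, MT-ND3 by 0.35 and MT-ND1 by 0.37 on the log2 scale. Without siNC replicate 1, siNC replicate 3 or siTRIM8 replicate 3 the number that fell was 4 in each case, as it was without the filter and without a trend. That list's median was −0.17, with camera adjusted p = 0.0103 and adjusted p = 0.420 with an estimated correlation. The call was also lost under median-of-ratios scaling (adjusted p = 0.112) and with siTRIM8 replicate 1 as the single siTRIM8 library (adjusted p = 0.0722). Mitochondrial transcripts made up between 4.11% and 4.39% of TPM in siNC and between 3.41% and 3.89% in siTRIM8.

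Of 44 cytosolic ribosomal protein genes, 14 rose, 1 fell and 29 did not pass (15 and 1 adjusted over the list alone). RPL22, RPL8, RPS16 and RPL37 rose by 0.25, 0.17, 0.14 and 0.14 on the log2 scale. The median was 0.07, with camera adjusted p = 3.53e-05 and adjusted p = 0.350 with an estimated correlation. Without siNC replicate 1, 2 or 3 the number that rose was 8, 8 and 7, and without siTRIM8 replicate 3 it was 4. The number that fell was 0 in these fits, without siTRIM8 replicate 1 and with the replicate block, where 9 rose. In the fit without a trend 1 member rose, and RPL8, RPS16 and RPL37 lost their calls (adjusted p = 0.0530, 0.0806 and 0.0842). Without the filter on low values 3 rose, and RPL8 and RPS16 lost theirs (adjusted p = 0.0545 and 0.0561). The RPL37 call was also lost under quantile normalization (adjusted p = 0.0877) and without siTRIM8 replicate 3 (adjusted p = 0.0554). Scaling moved this list. Median-of-ratios scaling gave 28 members higher and 0 lower, and quantile normalization 10 higher and 3 lower with the camera call lost (adjusted p = 0.109). Of 24 genes of cholesterol synthesis and uptake, 7 rose, 5 fell and 12 did not pass (9 and 6 adjusted over the list alone). MSMO1 and FDPS rose by 0.45 and 0.28, and the enzymes TM7SF2 and LSS fell by 0.74 and 0.39 on the log2 scale. Median-of-ratios scaling gave 11 higher and 3 lower, and the number that fell was also 3 without siNC replicate 1, siNC replicate 2 or siTRIM8 replicate 3, without the filter and without a trend. It was 2 with the GC and length trend removed. The median was 0.05, with camera adjusted p = 0.0408 and adjusted p = 0.424 with an estimated correlation. Fry did not call the list (fry adjusted p = 0.135). Its call was also lost under quantile normalization (adjusted p = 0.177), with a minimum mean of 10 TPM (adjusted p = 0.151), with siTRIM8 replicate 1 as the single siTRIM8 library (adjusted p = 0.144), and without siNC replicate 1, siNC replicate 3 or siTRIM8 replicate 2 (adjusted p = 0.0870, 0.0743 and 0.0816).

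Genes of the TGF-beta and BMP response fell in 7 of 14 cases, 0 rose and 7 did not pass (9 and 0 adjusted over the list alone). The inhibitors of differentiation ID1 and ID3 fell by 0.73 and 0.69, the SMAD corepressor gene SKIL by 0.59 and the inhibitory SMAD gene SMAD6 by 0.41 on the log2 scale. The SMAD6 call was lost without siNC replicate 2 (adjusted p = 0.0502) and without siTRIM8 replicate 3 (adjusted p = 0.0537), and with the GC and length trend removed (adjusted p = 0.0588). Without siNC replicate 1, 2 or 3 the number of list members that fell was 4, 3 and 4, and without siTRIM8 replicate 3 it was 3. It was 4 under median-of-ratios scaling and 3 with the GC and length trend removed. The median was −0.38, with camera adjusted p = 0.0129 and adjusted p = 0.409 with an estimated correlation. Of 25 autophagy and lysosome genes, 11 fell, 0 rose and 14 did not pass (11 lower and 1 higher adjusted over the list alone). GBA1, the lysosomal glucocerebrosidase, went from 81.6 ± 2.86 to 48.1 ± 0.768 TPM (log2 fold change −0.75, adjusted p = 0.000243). The cathepsin genes CTSL and CTSA fell by 0.54 and 0.36, and the proton pump subunit ATP6V0D1 by 0.28 on the log2 scale. Median-of-ratios scaling called 2 members higher and 8 lower, and quantile normalization 2 higher and 11 lower. The median was −0.27, with camera adjusted p = 0.0155 and adjusted p = 0.350 with an estimated correlation.

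The other 10 lists were not called by camera, though fry called some of them, as given below. In JAK-STAT signalling (20 tested, 3 higher, 7 lower, the same counts adjusted over the list alone, camera adjusted p = 0.580), SOCS3 and the kinase gene TYK2 fell by 1.09 and 0.39 and the phosphatase gene PTPN11 rose by 0.26 on the log2 scale. The number that fell was 4, 3 and 4 without siNC replicate 1, 2 or 3 and 4 without siTRIM8 replicate 3, and it was 4 under median-of-ratios scaling, with a minimum mean of 10 TPM and with the GC and length trend removed. Among p53 targets (32 tested, 11 higher, 6 lower, the same adjusted over the list alone, adjusted p = 0.0853), TP53INP1 and BTG2 fell by 1.65 and 0.70 while AEN and CCNG1 rose by 0.72 and 0.58. The p53 list was called with a minimum mean of 10 TPM (adjusted p = 0.0318). NF-kappaB targets (19 tested, 5 higher, 3 lower, the same adjusted over the list alone, adjusted p = 0.0925) included the low-level cytokine genes CXCL8, CXCL3, TNF and CXCL2, which rose by 1.58, 1.19, 1.10 and 1.06. The CXCL2 call was lost without siNC replicate 1 or 2 (adjusted p = 0.0538 and 0.0521). In that list 3 rose and 1 fell without siNC replicate 1 or 2, the number that fell was 1 in every leave-out of 1 library and under both other scalings, and 0 rose with a minimum mean of 10 TPM. It was called without siTRIM8 replicate 1 (adjusted p = 0.00876) and without siNC replicate 2 (adjusted p = 0.0457). In the apoptosis machinery (21 tested, 3 higher, 6 lower, 3 and 7 adjusted over the list alone, adjusted p = 0.616), BIK, MCL1 and BCL2L1 fell by 1.16, 0.66 and 0.60 and CYCS, which encodes cytochrome c, rose by 0.77.

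MAPK-responsive genes (11 tested, 2 higher, 3 lower, the same adjusted over the list alone, adjusted p = 0.856) moved both ways, with DUSP4, IER2 and PHLDA1 down by −1.26, −0.40 and −0.85 and JUN up by 1.09. Replication-dependent histone genes (10 tested, 1 higher, 5 lower, 2 and 6 adjusted over the list alone) had a median of −0.52 and adjusted p = 0.0629, with H2BC4, H2BC5, H2BC12 and H2AC20 at −0.92, −0.83, −0.58 and −0.94. That list was called under median-of-ratios scaling (adjusted p = 0.0251), under quantile normalization (adjusted p = 0.0441), and without siNC replicate 2 (adjusted p = 0.0348) or siTRIM8 replicate 2 (adjusted p = 0.0456). It was also called with a minimum mean of 10 TPM (adjusted p = 0.0121, median −0.71), with the GC and length trend removed (adjusted p = 0.0374), and with siTRIM8 replicate 1 as the single siTRIM8 library (adjusted p = 0.0175). Basal and mesenchymal markers (7 tested, 1 higher, 2 lower, 1 and 4 adjusted over the list alone, adjusted p = 0.580) included VIM and CDH3, which fell by 0.63 and 0.48, CD44, which rose by 0.42, and FN1, at −0.83 with adjusted p = 0.0545. The CD44 call was lost without siNC replicate 1 or 3 (adjusted p = 0.0771 and 0.0717), without siTRIM8 replicate 1 or 3 (adjusted p = 0.0581 and 0.0980), without the filter on low values (adjusted p = 0.0688), with the replicate block (adjusted p = 0.0691), and with siTRIM8 replicate 1 as the single siTRIM8 library (adjusted p = 0.183). FN1 passed without siTRIM8 replicate 2 (adjusted p = 0.0377). TRIM family paralogs (36 tested, 3 higher, 9 lower, the same adjusted over the list alone, adjusted p = 0.850) had a median of −0.06, a mean of 0.02 and a test direction of down, and the median was 0.02 under median-of-ratios scaling. Among them TRIM41, TRIM24 and TRIM44 fell by 0.34, 0.32 and 0.61 and TRIM36 rose by 0.38. Median-of-ratios scaling gave 6 higher and 5 lower, and quantile normalization 5 and 7. Without siTRIM8 replicate 1, 8 rose and 10 fell, the number that rose was 1 in each of the other leave-outs, and the number that fell was 4 without siNC replicate 1 and 5 without siTRIM8 replicate 3.

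Nuclear-retained and long non-coding RNAs (8 tested, 2 higher, 2 lower, 4 and 2 adjusted over the list alone, adjusted p = 0.160) included SNHG1 and OIP5-AS1, which rose by 0.77 and 0.65, and NORAD and TUG1, which fell by 0.57 and 0.35. The number that rose was 4 without siTRIM8 replicate 1 and under median-of-ratios scaling. Common reference genes (12 tested, 4 higher, 0 lower, the same adjusted over the list alone, adjusted p = 0.110) included HPRT1, GAPDH, TBP and TFRC, which rose by 0.64, 0.54, 0.26 and 0.25. The list was called under median-of-ratios scaling (adjusted p = 0.0235) and with the GC and length trend removed (adjusted p = 0.0484). The GAPDH call was lost without any 1 of the siNC libraries (adjusted p = 0.0925, 0.0677 and 0.0696) and without siTRIM8 replicate 3 (adjusted p = 0.0822), where the number of reference genes that rose was 2, 1, 2 and 2, and also without the filter (adjusted p = 0.0832). The TFRC call was lost in the same 4 leave-outs (adjusted p = 0.0714, 0.0582, 0.0815 and 0.0848), without siTRIM8 replicate 1 (adjusted p = 0.0505), with the replicate block (adjusted p = 0.0503), without a trend (adjusted p = 0.0559) and without the filter (adjusted p = 0.0585). TBP lost its call without siNC replicate 2 (adjusted p = 0.0507). Of 27 markers of non-epithelial cells 4 were tested, too few for a list test. HBA1, a hemoglobin gene, fell by 0.34 (adjusted p = 0.00599), while COL1A1, ACTA2 and HBA2 had log2 fold changes of 0.25, −0.14 and −0.09 and did not pass. COL1A1 was called under median-of-ratios scaling (adjusted p = 0.0204), quantile normalization (adjusted p = 0.0251), a minimum mean of 10 TPM (adjusted p = 0.0454) and with the GC and length trend removed (adjusted p = 0.00925). With that trend removed the HBA1 call was lost (adjusted p = 0.0608). Summed over the 27 markers, TPM lay between 54.3 and 57.2 in siNC and at 49.6, 58.4 and 50.7 in siTRIM8 replicates 1, 2 and 3.

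The preset-correlation camera test called 14 of 24 lists, 10 up and 4 down, with 0 called under an estimated correlation. The respiratory chain list lost its call there (camera adjusted p = 0.145) although its estimated correlation, 0.00685, was below the preset 0.01. A lost call in that setting therefore does not by itself show that the members vary together. Fry, which asks whether a list's genes move one way and does not compare them with other genes, called 18 lists. Of the lists called by camera, fry did not call the interferon-stimulated genes (fry adjusted p = 0.121) or the cholesterol genes (fry adjusted p = 0.135). Of the lists camera did not call, fry called these as down: apoptosis machinery (fry adjusted p = 0.00263), histones (0.00258), JAK-STAT signalling (0.0149) and basal markers (0.0209). It called common reference genes (fry adjusted p = 0.0103) and long non-coding RNAs (0.0328) as up. Other divisions of the 6 libraries into 3 and 3 each gave between 6 and 13 list calls with the preset correlation and 0 called genes. A list call at the preset correlation is thus not particular to the real grouping. Each of these other divisions mixes both groups, which widens the spread, so few called genes were to be expected there.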

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

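Alternatives with siTRIM8 replicates 2 and 3 left out and with the GC and length trend removed were chosen after the data were seen; in the former the lone siTRIM8 library is assumed to vary like the siNC libraries. TRIM8 fell past the threshold in all alternatives run. The number of genes at least 2-fold changed was 644 with a pseudocount of 0.1, 104 with a pseudocount of 5 and 148 with a minimum mean of 10 TPM, against 354; a larger pseudocount shrinks folds of low genes by construction. The number of called genes ranged from 3083 (without siNC replicate 2) to 4493 when 1 library was left out, was 3176 without siTRIM8 replicate 3, and was 2592 with siTRIM8 replicates 2 and 3 left out, where fewer libraries were compared. With an estimated correlation 0 lists were called, and the estrogen-induced list (median 0.53) had adjusted p = 0.141.

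The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.00, 0.04 and −0.04, and 2 of 6 libraries correlated best with their own number. With the replicate block 3851 genes, 341 at least 2-fold, and 14 lists were called.

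Test directions, which need not follow the median, reversed for lists and a gene that were not called, and the cause was not tested. They were basal and mesenchymal markers (median −0.0039) and MAPK-responsive genes (−0.0371) without the filter, NF-kappaB targets (−0.13) with siTRIM8 replicates 2 and 3 left out, and HBA2 under quantile normalization (0.0526) and with the GC and length trend removed (0.0511). Leaving out 1 library, camera's direction reversed for MAPK-responsive genes without siNC replicate 2 (median −0.14) or siTRIM8 replicate 1 (−0.17), and for TRIM paralogs without siTRIM8 replicate 1 (−0.0492), while HBA2 was positive without siNC replicate 1 (0.0197), siNC replicate 2 (0.0108) or siTRIM8 replicate 1 (0.14). Over the 6 leave-outs medians ranged from −0.22 to −0.14 for MAPK-responsive genes and from −0.0902 to −0.0258 for TRIM paralogs, and HBA2 ranged from −0.31 to 0.14. Among 116 named genes, 143 of their alternative results lost the call, 5 gained it and 1795 kept direction and call. Depth could not be examined, and count tests were not run, since TPM are not read counts.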

Other observations

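The gene groups and named genes in the next paragraph were picked after the values were seen, so their counts are not independent evidence. Of the tests that follow, the count over other splits was fixed in advance. The removal of the GC and length trend was added after the data were seen, with its bounds set before its result, and the other tests and their bounds were chosen after their results were seen.

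Interferon genes themselves were near 0 in siNC. IFNB1 stood at 0.1, 7.15 and 2.62 TPM and IFNL1 at 0.12, 20.7 and 8.4 TPM in siTRIM8 replicates 1, 2 and 3 (limma adjusted p = 0.101 and 0.102). IFNL2, at 0.64, 7.71 and 5.13 TPM in the same libraries, passed (limma adjusted p = 0.0452). IFNL3, at 0.26, 9.96 and 5.29 TPM there, did not (limma adjusted p = 0.0730). Its log2 fold change, 2.03, was no smaller than the 1.88 of IFNL2, so these results do not set the genes apart. Of 11 tested MHC class I and antigen processing genes 5 rose and 1 fell, with HLA-B up from 9.11 ± 1.03 to 29.2 ± 8.72 TPM (log2 fold change 1.54, n = 3, limma adjusted p = 0.00328), while ERAP1, a peptide-trimming enzyme, fell by 0.83 on the log2 scale. Of 8 genes known to be repressed by estrogen 7 fell and 0 rose, among them YPEL3 (−1.90), BCAS1 (−1.55) and BMF (−1.03). Of 8 tested potassium channel genes 2 rose and 4 fell, among the latter KCNK12 (−1.99) and KCNJ8 (−1.55).

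Interferon-stimulated genes were higher in siTRIM8 replicates 2 and 3 than in siTRIM8 replicate 1. Removing the GC and length trend left the median at 1.87, which argues against that bias as the whole cause. Among markers near 0 in siNC, the highest class median in replicates 2 and 3 was 0.13 TPM. The median rise of the interferon-stimulated genes there was at least 18.8 TPM. PTPRC stood at 0 and 0, LYZ at 0.13 and 0.14 and COL1A2 at 0.76 and 0.33 TPM. These values argue against many fibroblasts, lymphocytes or endothelial cells, but cannot exclude a few strongly responding ones. Myeloid cells remain undecided. CD68 reached 3.35 and 1.55 TPM, from at most 0.73 in siNC, while PTPRC and LYZ did not rise. Cells of another type without such markers, such as other epithelial cells, cannot be told apart from a response of these cells, and the sum over all markers, 58.37 TPM in siTRIM8 replicate 2 against 57.2 in the highest siNC library, was mostly carried by HBA1 and COL1A1, already present in siNC. TRIM8 differed by 0.33 on the log2 scale among the siTRIM8 libraries, too little to relate its level to the interferon response. A response to the transfected duplex cannot be told apart from an effect of TRIM8 loss with 1 siTRIM8 group. The median shift in replicate 1 was a share of 0.122 of that in replicates 2 and 3. It favours neither, since replicate 1 carries the same siTRIM8 label. TRIM8 stood at 3.2, 2.88 and 3.89 TPM in siTRIM8 replicates 1, 2 and 3, so its level does not set replicate 1 apart. Differences between cultures remain open and were not tested.

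Estrogen-induced genes were higher in all 3 siTRIM8 libraries. A rise secondary to the interferon response, and in proportion to it, would be small in siTRIM8 replicate 1. The median shift of the estrogen-induced genes there was a share of 0.822 of that in replicates 2 and 3. For the interferon list the share was 0.122, so the lists did not shift in proportion. This cannot exclude a secondary rise of another form. It rests on 1 library, where 18 of 34 interferon-stimulated genes also lay above all 3 siNC libraries. Its bound was set after the share was seen. Removing the GC and length trend left the median at 0.60. An effect of TRIM8 loss and an off-target effect of the siRNA both remain open and were not tested.

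Genes of hypoxia and glycolysis were shifted least in siTRIM8 replicate 1. Of the 22 members, 19 lay above all 3 siNC libraries in that replicate, where chance gives 25% for each gene. The members vary together (estimated correlation 0.835), so they are not independent counts. From 1 library, this cannot decide whether the change was in replicates 2 and 3 alone. Removing the GC and length trend left the median at 1.06. An effect of TRIM8 loss, a response to the duplex and differences between cultures remain open and were not tested.

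The 6 libraries divide into 10 splits of 3 and 3, too few for a share under 0.05. The real split gave 4776 genes, 354 at least 2-fold and 14 lists. The highest of the other splits gave 0, 0 and 13, and 1 of the 10 splits gave as many in each case. For 13 of the 14 called lists the absolute median was largest in the real split, a count made after the results were seen. Every other split mixes libraries of both groups, so a group difference widens the spread within its sides. Fewer called genes and smaller medians there were therefore to be expected. The 14 lists were also those called in the real split, so these counts decide nothing about chance.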
